A study of Mus musculus with 8 samples.

How the data were processed

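Total RNA of R1 mouse embryonic stem cells differentiated in embryoid bodies was measured on 8 Agilent 1-colour (Cy3) arrays, 48 h after transfection. The sample titles gave the groups, with 3 arrays of Control siRNA, 3 of siRNA 1 and 2 of siRNA 2. Each deposited scanner file held 44397 spots of 1 array as intensity values, extracted by the authors with Agilent Feature Extraction 10.7.3.1, per the file headers. The processed intensity was already corrected for background in those files, per the file headers, and had not been scaled between arrays. The median spot and background intensity and the flags for spots well above background and for outliers were taken from the deposited files as well, and 0 spots were saturated.

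A deposited value table held log2 values of the same arrays. Set against the scanner files, its columns followed log2 processed signal minus the array's 75th percentile, with each probe centred on its median over the 8 arrays. Column medians lay between -0.04 and 0.02, and scale, centring and direction were thereby known. The submitters' processing notes name RMA with no role, and the column medians were not equal. The columns named Control 2 and Control 3 followed each other's scanner file, with r = 1 across probes against the other array and r = -0.05 against their own. Both arrays belong to Control, so the fit without blocks does not depend on this, but the block on replicate numbers does. Scanner file names were used.

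Control spots and outlier spots were left out, and spots of 1 probe were averaged. Accessions in the scanner files were matched to gene symbols through a RefSeq table of assembly GRCm38.p6, without versions. Of 39429 probes, 26424 matched a symbol and 13005 are unnamed here. The array design used build mm9, so no coordinates are given. Where a gene had several probes, the probe with the highest mean over all 8 arrays was used. A gene was tested if its probe was well above background on every array of at least 1 group, which left 27389 probes and 22425 genes, 15569 of them with a symbol.

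The main values were log2 processed signal minus the 75th percentile of each array. One fit over the 3 groups was made with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 with statmod 1.5.0, with 5 residual and 2.12 prior degrees of freedom. It gave the mean of both siRNAs against Control, each siRNA against Control, and siRNA 2 against siRNA 1. Benjamini-Hochberg adjusted p under 0.05 was the threshold. Gene lists were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry beside it, over 29 lists for cell types, pathways and stress responses that were written before the data were examined. A gene not well above background on any array of a group has only a bound there. It is given as at least N-fold, the brighter group's mean against the dimmer group's mean of the higher of the probe's own signal and the array's lowest signal well above background, on normalized log2 values. Ppp3cb and its relatives were tested with an exact two-sided permutation test of the 5 siRNA arrays against the 3 Control arrays, and with the Control label permuted within slides, a test added after the values were seen.

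Genes to be named were set by a rule before the data were examined. It takes the calcineurin genes, the genes past the threshold with the largest differences, or, where none passes, the 5 with the smallest p in each direction, and for each list the members past the threshold or the 2 with the smallest p. Some genes that the rule takes are not reported here, and counts include them. Other genes were chosen after their values were seen, and these are T, Gata6 and Sox17 in the report and the genes that the closing section names as such.

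The fit was tested on simulated data with known changes over 20 draws per comparison and fold size, with variances drawn from limma's fitted prior. It was first judged on 1 draw each, where 1 setting exceeded its limit on false calls, and the number of draws and the variances were changed after that was seen. Of 200 genes changed by 2-fold among 22425, 67.5% were recovered for the mean of both siRNAs, 59.2% for siRNA 1, 47.9% for siRNA 2 and 48.1% for the difference between siRNAs. Between 3.88% and 5.43% of calls were false. The simulation had independent arrays with no slide effect. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the files and drew the plots.

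Alternatives were quantile normalization, median scaling, normexp background correction with an offset of 50 followed by quantile normalization, no background correction, the deposited value table, other filters on dim probes, all probes or their mean, only the groups compared in the fit, a variance trend with robust estimation, array weights, the replicate number or the slide as a block, a minimum of 1.5-fold, 1 pooled siRNA group, and leaving out each array. The plan named the mean spot signal for normexp and for no background correction, and the median spot signal took its place, a departure from the plan. Scan batch and slide split the arrays in the same way and were tested once. Leaving out the arrays of slide 1 was added after seeing the data.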

Results

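R1 mouse embryonic stem cells, a pluripotent line that forms embryoid bodies when grown in suspension, had received a control siRNA or an siRNA against CnAβ1. CnAβ1 is a splice variant of the calcineurin Aβ catalytic subunit, which the gene Ppp3cb encodes. The cells were differentiated as embryoid bodies for 48 h in all samples. Total RNA was taken 48 h after transfection and hybridised to 1-colour Agilent arrays. There were 3 Control arrays, 3 arrays of siRNA 1 and 2 arrays of siRNA 2. Between 68.0% and 75.1% of the 43020 spots other than control spots were well above background on each array, and 22425 genes were tested. The 75th percentile of the processed signal lay between 838 and 1031, and the number of arrays limits the precision of every value below. Nothing in the labels says that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

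The 8 arrays lay on 3 slides, and the arrays of slide 1 stood apart from the rest. Slide 1 held replicate 1 of each group, slide 2 held Control 2 and replicate 3 of siRNA 1, and slide 3 held Control 3 and replicate 2 of each siRNA. The first principal component took 41.0% of the variance and separated the slide 1 arrays, whose scores lay between 30.2 and 36.6, from the others, which lay between -25.9 and -14.0. Within groups, 1273 genes differed between slide 1 and the other slides in limma's test, and 1119 of them were lower on slide 1. Every Control array lay at position 1 of its slide, every siRNA 1 array at position 2 and every siRNA 2 array at position 3.

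**Figure D1:**
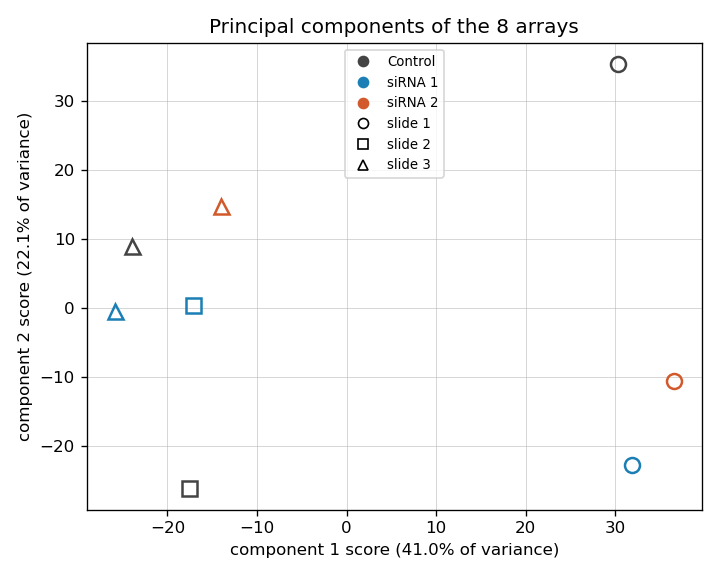
Scores of the 8 arrays on component 1 (41.0% of the variance) and component 2 (22.1%), both unitless, from log2 signals relative to the array's 75th percentile, with colour for the group and marker shape for the slide. The 3 arrays of slide 1 lie between 30.2 and 36.6 on component 1, and the other arrays lie between -25.9 and -14.0.

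The first question was whether the target was lower in the knockdown arrays. One probe was named for Ppp3cb, by the conventional transcript of the gene (probe A_52_P306396). It is not known here whether the probe reads the CnAβ1 variant, so it checks nothing about that variant. Its log2 signal relative to the array's 75th percentile was 0.72 ± 0.12 in Control (SD, n = 3), 0.47 ± 0.20 in siRNA 1 (SD, n = 3) and 0.60 ± 0.14 in siRNA 2 (SD, n = 2). The siRNA arrays were lower by a log2 difference of -0.20, and 5 of 5 lay below the Control mean, with an exact two-sided permutation p of 0.143 over 56 splits. Within slide 1 the siRNA arrays differed from Control by -0.57 and -0.35, within slide 2 by 0.07 and within slide 3 by -0.24 and -0.01. In limma's fit the difference moved from -0.18 to -0.12 without Control replicate 1, and it ranged from -0.24 to -0.02 over the alternatives. Ppp3ca, which encodes the Aα catalytic subunit, was higher by 0.49, with an exact permutation p of 0.0357 over splits that ignore the slides and limma's adjusted p of 0.9999 over all genes. Permuted within slides, where 18 placements allow no exact p under 0.0556, its exact p was 0.111, and on slide 2 it differed by -0.05. Ppp3cc, the γ catalytic subunit, differed by -0.23 (exact p = 0.232), which came from slide 1, as the differences on the other slides lay between -0.02 and 0.04. Ppp3r1, the regulatory B subunit, differed by 0.03 (exact p = 0.857) and turned to -0.02 in the fit without Control replicate 3. Without Control replicate 1 the fitted difference of Ppp3cc was -0.11 and that of Ppp3ca 0.33. Over the alternatives they ranged from -0.31 to 0.01 for Ppp3cc and from 0.25 to 0.69 for Ppp3ca. Of the 14 measured calcineurin subunits and regulators, none passed the threshold over all genes or adjusted over the list alone.

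The main comparison took the mean of both siRNAs against Control, which 1 siRNA can carry. Primitive and visceral endoderm genes, markers of the extraembryonic layer of the embryoid body, stood lower in 17 of 18 measured members, with a median log2 difference of -0.61, or -0.35 without Control replicate 3. Naive pluripotency genes stood higher in 18 of 20 members, with a median of 0.21, ranging from 0.07 to 0.46 over the alternatives. The highest value came without Control replicate 2, whose own list median stood at 0.44 against the Control mean. The siRNA arrays stood between 0.14 and 0.72 on that scale, and only siRNA 1 replicate 1 lay above Control 2. Definitive endoderm genes were lower in 11 of 12 members (median -0.20, ranging from -0.47 to -0.11 over the alternatives). Primitive streak and mesoderm genes were lower in 17 of 25 (median -0.10, or -0.05 without siRNA 2 replicate 2 and -0.19 without Control replicate 1). In the primitive and visceral endoderm list the median was -1.12 under siRNA 2 and -0.24 under siRNA 1, and in the mesoderm list -0.27 and -0.04. No single gene passed limma's threshold, so the values of single genes in these lists describe the arrays only.

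Insm1, a zinc finger transcription factor of neuroendocrine cells, had the smallest p and was higher by a log2 difference of 0.97 ± 0.10 (SE, n = 5 and 3), or 1.96-fold. The SE of the other 8 genes named here lay between 0.06 and 0.18. Fbp1, an enzyme of gluconeogenesis, was higher by 0.60, Gadd45g, a stress-response gene, by 0.61, Rassf9 by 0.54 and Nqo1, a quinone reductase, by 0.48. On the lower side were Tmem176a at -0.98 (-0.19 under normexp), Col6a1, a collagen VI chain, at -0.68, Plpp6 at -0.41 and Rreb1 at -0.40. For each of these 9 genes, all 5 siRNA arrays lay on the same side of all 3 Control arrays, as did 3.23% of all genes against 3.57% by chance. Under normexp the differences of Rassf9, Rreb1 and Plpp6 were 0.31, -0.26 and -0.16. Limma's adjusted p was 0.341 for the 5 higher genes and between 0.610 and 0.737 for the 4 lower genes.

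Limma called 0 of the 22425 genes. At an unadjusted p under 0.05 there were 462 higher and 331 lower genes, 793 in all against 1121 by chance. With array weights 23 genes were called, among them Insm1, Fbp1, Gadd45g, Rassf9, Nqo1, Rreb1 and Plpp6, so that for these genes the call depended on this setting. In arrays simulated for this comparison over 22425 genes, 67.5% of 200 genes changed by 2-fold and 92.7% of 200 changed by 4-fold were recovered. The simulated arrays had no slide effect, so these shares do not say how many such changes would be found in the real arrays. In the real arrays 20 genes were higher and 20 lower by at least 2-fold, none of them called.

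Of 29 lists, 10 shifted in limma's camera test with a preset correlation, 3 of them higher and 7 lower, and 0 were called with an estimated correlation. The primitive and visceral endoderm list had an adjusted p of 5.48e-10 and the naive pluripotency and definitive endoderm lists both of 4.04e-06. The remaining lower lists were primitive streak and mesoderm (adjusted p = 0.000222), Hox genes (median -0.14), fibroblast feeder cells (-0.09), Wnt/beta-catenin targets (-0.08) and Nodal and Smad2/3 targets (-0.05). The remaining higher lists were glycolysis and hypoxia (median 0.08) and cytosolic ribosomal proteins (0.09 in 19 of 21 members), the latter turning to -0.01 under quantile normalization and under normexp. With an estimated correlation the lists had adjusted p = 0.353 for definitive endoderm and for mesoderm and adjusted p = 0.398 for the other 8, and fry called 0. With slide as a block 8 lists were called, glycolysis and hypoxia and Nodal and Smad2/3 targets having lost their call.

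The calls differed in how far they rested on single arrays. The primitive and visceral endoderm, definitive endoderm and mesoderm lists kept their call under the preset correlation with every other processing choice and with any 1 array left out. The naive pluripotency list lost its call without the arrays of slide 1, where its median was 0.07. Without Control replicate 1, and likewise without siRNA 1 replicate 2, 5 lists were called, the Hox, fibroblast, Wnt, Nodal and glycolysis lists having lost their call. At least 1 of these 5 lists also lost its call without each of the other arrays, and the glycolysis list lost it in 15 of 23 alternatives, the Hox and Wnt lists each in 8, the fibroblast list in 6 and the Nodal list in 5. With 1 array left out the medians ranged from -0.23 to -0.08 for the Hox list, from -0.17 to -0.05 for the fibroblast list and from -0.21 to -0.04 for the Wnt list. The Nodal median turned to 0.01 without siRNA 1 replicate 2 and to 0.01 without siRNA 2 replicate 2.

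Adjusted over the list alone, 9 members were called and 0 over all genes. Among the naive pluripotency genes, Fgf4 rose by 0.43 and Gbx2 by 0.47, both with limma's adjusted p of 0.0145 over the list alone. Among the mesoderm genes, Fgf8, a primitive streak growth factor, fell by 1.09 on the log2 scale and Flt1, a VEGF receptor, by 0.40. In the cardiac and vascular list, whose median was -0.06, the smooth muscle genes Tagln and Acta2 fell by 0.57 and by 0.52. In the fibroblast list, the calls were Col6a1 and Fap, a fibroblast surface protease that was not well above background on any siRNA array.

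The other 19 lists did not pass. Their medians were 0.16 for the interferon response, 0.12 for trophectoderm, 0.11 for BMP and Smad1/5 targets, 0.06 for germ cells, 0.03 for neuroectoderm and 0.02 for oxidative phosphorylation and for the 2-cell-like state. The calcineurin list stood at -0.04 and the cardiac and vascular list at -0.06. The medians of histone genes, cell cycle, mTOR complex components, formative and primed epiblast, FGF/ERK targets, FoxO targets, p53 targets, the COG complex and Golgi structure, cholesterol synthesis and the ATF4 and unfolded protein response lay between -0.03 and 0.01. In the epiblast, cholesterol, p53 and ATF4 lists the median and camera's direction differed in sign.

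**Figure D2:**
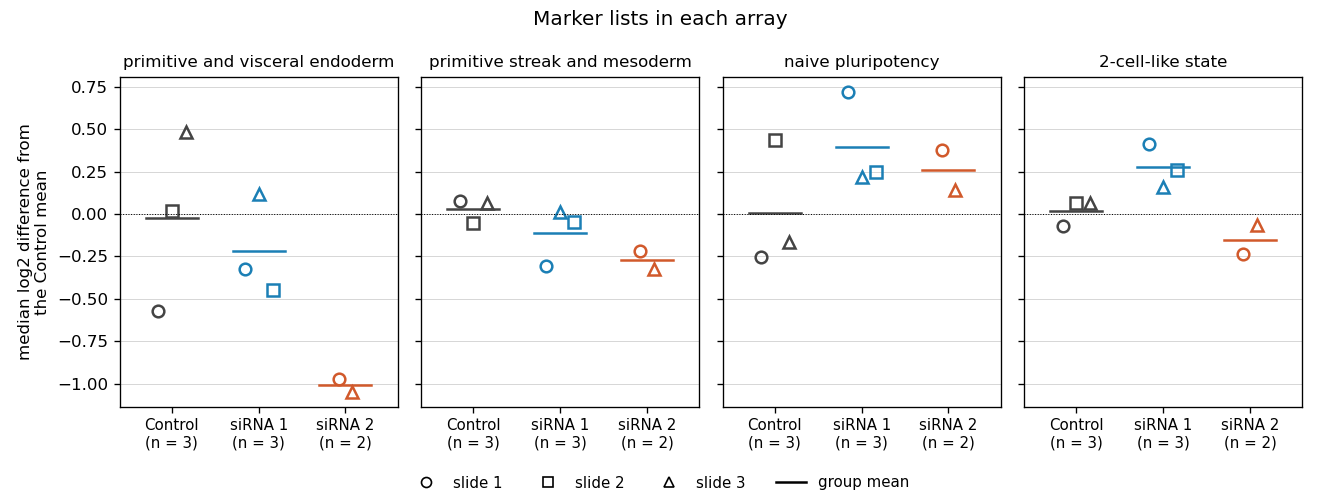
Each point is 1 array's median log2 difference from the Control mean over the measured members of a list (y axis, log2 units), by group (x axis), with marker shape for the slide and a line at the group mean. In the primitive and visceral endoderm list the siRNA 2 arrays stand at -0.97 and -1.05, below the lowest Control array at -0.57.

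The comparison of siRNA 1 with Control took 3 arrays against 3. The naive pluripotency list stood higher in 18 of 20 members with a median of 0.41 (0.17 without siRNA 1 replicate 1), and the 2-cell-like list, genes of the 2-cell embryo, in 8 of 9 with a median of 0.29. Definitive endoderm genes were lower in 11 of 12 members with a median of -0.24, which was -0.06 without Control replicate 3 and 0.01 within slide 1. Primitive and visceral endoderm genes were lower in 14 of 18 members with a median of -0.24, which was 0.18 within slide 1 and -0.61 and -0.37 within slides 2 and 3, and that list did not pass. Nor did primitive streak and mesoderm genes, of which 11 were higher and 14 lower (median -0.04). The median of the cardiac and vascular list was 0.08 while its mean was -0.14. Fbp1 was higher by 0.70 ± 0.07 (SE, n = 3 and 3), Fank1 by 0.89, Gfra3, a GDNF family receptor, by 0.74 and Gadd45g by 0.62. Tmem176a was lower at -1.12 (-0.20 under normexp), Col6a1 at -0.81, Lats2, a Hippo pathway kinase, at -0.62 and Gucy1a2 at -0.40, and Fap was at least 1.60-fold lower, a bound set by signals near background. Under normexp Fank1 stood at 0.36, Lats2 at -0.33 and Gucy1a2 at -0.15, and the other probe of Lats2 stood at -0.39.

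Limma called 0 genes here, with 748 at an unadjusted p under 0.05 and a smallest adjusted p of 0.400. Camera called 5 lists, which were naive pluripotency (adjusted p = 5.98e-06), cytosolic ribosomal proteins (0.000386, median 0.10), fibroblast feeder cells (0.00383, median -0.06), definitive endoderm (0.00417) and the 2-cell-like state (0.00637). Each had an adjusted p = 0.466 with an estimated correlation. Within slides 1, 2 and 3 the naive pluripotency median was 0.91, -0.14 and 0.32, so that it turned on slide 2, and the 2-cell-like median was 0.51, 0.16 and 0.09. The naive pluripotency list lost its call without the arrays of slide 1, and the 2-cell-like list without those arrays, with array weights and without Control replicate 1. Definitive endoderm lost it without Control replicate 3 or siRNA 1 replicate 3, the fibroblast list without Control replicate 1 or siRNA 1 replicate 2 or 3, and ribosomal proteins without siRNA 1 replicate 2, under quantile normalization and under normexp. With 1 array left out the fibroblast median ranged from -0.20 to -0.03 and the ribosomal median from 0.06 to 0.15. Within slides 1, 2 and 3 the fibroblast median was 0.005, -0.27 and -0.10. Within groups the fibroblast list stood higher on slide 1 than on the other slides, by a median of 0.17. The ribosomal median turned to -0.00037 under quantile normalization. Adjusted over the list alone, Fgf4, Fap, Col6a1, Tagln and Acta2 were called, Tagln and Acta2 having fallen by 0.69 and by 0.71.

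With siRNA 2 against Control, 2 arrays against 3, the primitive and visceral endoderm list stood lowest. Primitive and visceral endoderm genes were lower in 17 of 18 members with a median log2 difference of -1.12, which stayed at -1.12 with Afp at its bound. Afp, the fetal serum protein alpha-fetoprotein, was not well above background on either siRNA 2 array and was at least 6.71-fold lower than in Control. That bound holds for the group means in the main processing only. The fitted log2 difference of Afp, -3.55, ranged from -4.16 to -0.90 over the alternatives. Within slides 1 and 3 Afp differed from Control by -4.81 and -2.41, and the latter is smaller than the bound. Gc, the vitamin D-binding protein, was lower by a log2 difference of -1.61 ± 0.23 (SE, n = 2 and 3), and its other probe by -0.95. Under normexp the Gc difference was -0.29, and those of Pde10a, Rreb1 and Rassf9 were -0.19, -0.40 and 0.40. Definitive endoderm genes were lower in 12 of 12 members (median -0.21), and primitive streak and mesoderm genes in 19 of 25 (median -0.27). Within slides 1 and 3 the mesoderm median was -0.09 and -0.32, and the definitive endoderm median was -0.24 and -0.25. Over the alternatives the definitive endoderm median ranged from -0.61 to -0.15. On the higher side, Insm1 differed by 1.18 ± 0.12 (SE), Nqo1 by 0.64, Rassf9 by 0.63, Prph, the intermediate filament peripherin, by 0.60 and Gadd45g by 0.60. Among the lower genes were also Pde10a at -0.74 and Rreb1 at -0.61 (-0.50 and -0.41 by their other probes), and the keratin Krt82 was at least 1.61-fold lower.

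Adjusted over the list alone, 14 entries passed against 0 over all genes. In the primitive and visceral endoderm list these were Afp, Ttr, the thyroid hormone carrier transthyretin, which fell by 1.83, and Cubn and Amn, the cubilin receptor and its partner, which fell by 1.25 and by 1.01. In the definitive endoderm list, Foxa2 fell by 1.54 and Trh by 1.06. In the mesoderm list, Evx1 fell by 1.64, Fgf8 by 1.36, Eomes by 0.80 and Flt1 by 0.48, and Eomes also passed in the Nodal list. Fgf4 and Gbx2 rose by 0.45 and by 0.55. The brachyury gene T stood at -1.01, Gata6 at -1.21 and Sox17 at -1.04, and these did not pass in any list. Under normexp Ttr stood at -1.12 and Evx1 at -0.68.

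**Figure D3:**
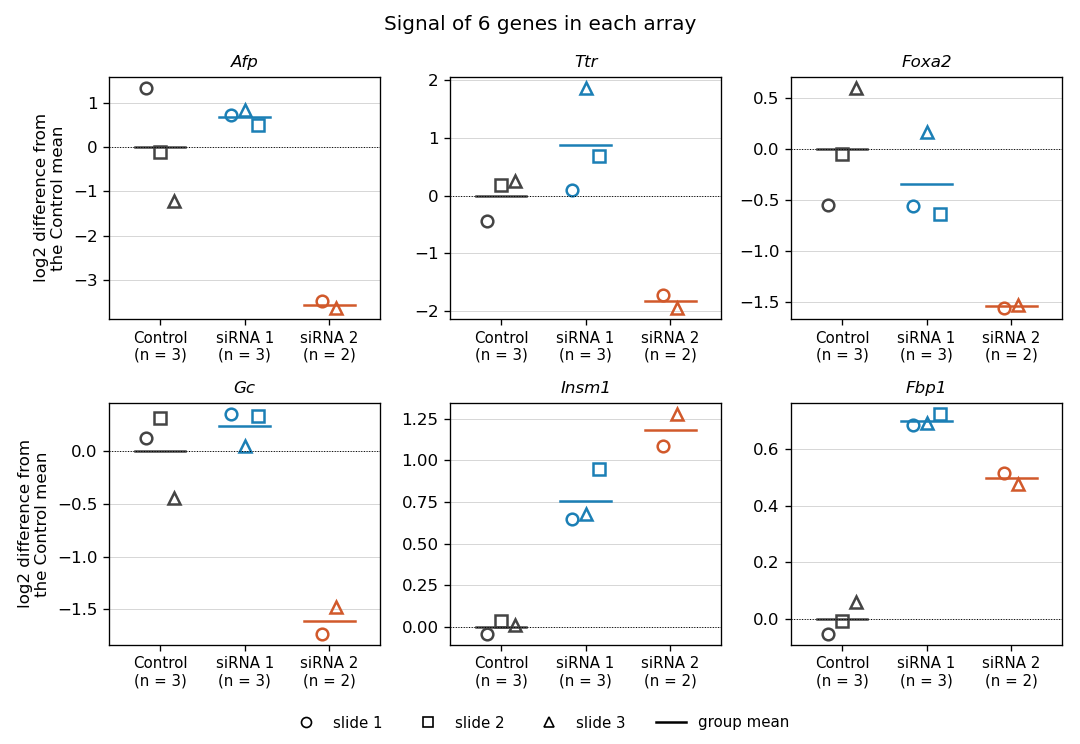
Each point is 1 array's log2 difference from the Control mean (y axis, log2 units, with its own range in each panel), by group (x axis), for Afp, Ttr, Foxa2, Gc, Insm1 and Fbp1, with marker shape for the slide and a line at the group mean. Afp stands at -3.48 and -3.62 in the siRNA 2 arrays, where it was not well above background, and between 0.50 and 0.84 in the siRNA 1 arrays. The Control arrays differ too, as siRNA 2 minus Control was -4.81 within slide 1 and -2.41 within slide 3.

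Limma called 0 genes for siRNA 2, with 786 at an unadjusted p under 0.05 and a smallest adjusted p of 0.490. Camera called 9 lists, 2 higher and 7 lower. The primitive and visceral endoderm list had an adjusted p of 2.54e-14, or an adjusted p = 0.349 with an estimated correlation. The definitive endoderm and mesoderm lists had adjusted p of 8.33e-06 and 8.45e-06, and for both an adjusted p = 0.195 with an estimated correlation. The other calls were naive pluripotency (median 0.21) and ribosomal proteins (0.08, turning to -0.0021 under quantile normalization and -0.02 under normexp), and the lower lists Nodal and Smad2/3 targets (-0.10), Hox genes (-0.13), Wnt/beta-catenin targets (-0.08) and the 2-cell-like state (-0.23). For those 6 lists camera's adjusted p was between 0.349 and 0.729 with an estimated correlation. Within slides 1 and 3 the primitive and visceral endoderm median was -0.45 and -1.82, and with slide as a block it was -1.19. The Hox, Nodal and Wnt lists lost their call in camera with that block.

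For siRNA 2 the primitive and visceral endoderm, definitive endoderm and mesoderm lists kept their call under the preset correlation with every other processing choice and with any 1 array left out. They are not independent, as the primitive and visceral endoderm list shares 3 genes with the definitive endoderm list and 2 with the mesoderm list. The naive pluripotency list, whose median ranged from 0.14 to 0.43 with 1 array left out, lost its call without Control replicate 1, without siRNA 2 replicate 1 and without the arrays of slide 1. Over all alternatives its median fell as low as 0.02, and within slides 1 and 3 it was 0.60 and 0.31. Against the Control mean, Control 2 stood at 0.44, above the siRNA 2 arrays at 0.38 and 0.14. Without siRNA 2 replicate 2 the ribosomal, Hox and Nodal lists lost theirs, and without siRNA 2 replicate 1 the Wnt and 2-cell-like lists. Leaving out Control replicate 1 ended the Hox, Nodal and Wnt calls, Control replicate 2 the Hox and 2-cell-like calls, and Control replicate 3 the Wnt and 2-cell-like calls. With 1 array left out the medians ranged from -0.37 to -0.05 for the Hox list, from -0.27 to -0.04 for the Nodal list, from -0.19 to -0.08 for the Wnt list, from -0.28 to -0.07 for the 2-cell-like list and from 0.05 to 0.13 for the ribosomal list. Of 23 alternatives, 10 ended the Wnt call, 8 the Hox call, 5 each the Nodal and 2-cell-like calls and 3 each the naive and ribosomal calls, reversals included. Limma called 2 genes without siRNA 2 replicate 1 and 5 without siRNA 2 replicate 2.

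The difference between the siRNAs was tested directly. The primitive and visceral endoderm genes were lower with siRNA 2 than with siRNA 1 in 18 of 18 members, with a median of -0.61, and the mesoderm genes in 21 of 25, with a median of -0.34. The 2-cell-like genes, several of which belong to families of near-identical copies that a probe may not tell apart, were lower in 8 of 9 members, with a median of -0.52. The formative and primed epiblast genes were higher in 12 of 17 members, with a median of 0.07. Afp was at least 10.8-fold lower in the main processing. Its fitted log2 difference, -4.24, ranged from -4.59 to -1.19 over the alternatives. Ttr differed by -2.71 and Gc by -1.85 ± 0.23 (SE, n = 2 and 3), or by -0.31 under normexp and -1.10 by its other probe. Usp17lb differed by -0.97 and Ntn1, the guidance factor netrin 1, by -0.49. Sema4f was higher by 0.47, Adamts10 by 0.36, Wnk4 by 0.32 and Nqo1 by 0.31. Under normexp Usp17lb stood at -0.42, Ntn1 at -0.13, Sema4f at 0.25, Wnk4 at 0.13 and Adamts10 at 0.05.

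Limma called 0 genes for this difference, with 777 at an unadjusted p under 0.05 and a smallest adjusted p of 0.551. With only these groups in the fit, 1 gene was called, Afp, and 2 and 4 genes were called without siRNA 2 replicate 1 and replicate 2. Camera's adjusted p was 1.05e-08 for primitive and visceral endoderm, 4.03e-05 for the 2-cell-like state, 0.00261 for mesoderm and 0.0386 for the epiblast list. With an estimated correlation these became an adjusted p = 0.629, 0.287, 0.539 and 0.775. Without siRNA 2 replicate 2 the mesoderm call was lost, with a median of -0.17, and the epiblast median turned to -0.06, and the epiblast call was lost without siRNA 1 replicate 1, under quantile normalization, under normexp and with array weights too, in 5 of 23 alternatives. Adjusted over the list alone, Afp, Ttr, Zscan4f, Zscan4a, Usp17la and Tcstv1 were called, Zscan4f moving from -0.56 to -0.35 without siRNA 2 replicate 1.

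The last comparison asked for genes moved the same way by both siRNAs, and 0 genes passed limma's threshold against Control with both. Across genes, which are not independent replicates, the log2 differences of siRNA 1 and siRNA 2 correlated at r = 0.40. Unchanged groups of the same sizes, simulated with a shared simulated Control group, gave 0.45, with a range of 0.42 to 0.48. The simulated arrays were independent and had no slide effect, unlike the real ones. The simulation therefore cannot show whether the siRNAs agree more or less than unchanged groups would. The covariance was 0.0167 against 0.0236 in the simulation, and 61.4% of genes had the same sign against 64.8%. With slide as a block the observed values were 0.46, 0.0190 and 62.5%, for which no simulation with a block was run. The 3 Control arrays cannot be split into parts of at least 2, so the share of the shared Control arrays in these values was not separated.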

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

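The tests of slide, of position, of the replicate 1 slide and of the 2 Control columns, and the count of splits for the siRNA 1 lists, were chosen only after the result was seen. A difference between the siRNAs in their effect against Control, tested directly, singled out 4 lists in camera at the preset correlation. Primitive and visceral endoderm genes differed by a median of -0.61, 2-cell-like genes by -0.52, mesoderm genes by -0.34 and formative and primed epiblast genes by 0.075. Their adjusted p was 1.05e-08, 4.03e-05, 0.00261 and 0.0386. With an estimated correlation none passed, at adjusted p = 0.629, 0.287, 0.539 and 0.775.

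The lower primitive and visceral endoderm genes under siRNA 2 were weighed against technical and biological explanations. Scaling and a single array are argued against as the whole of it, because the median stayed at or below -0.66 under 5 scaling and background settings and at or below -0.79 with any 1 array left out. The size of the difference moved with the slide, at -0.45 within slide 1 and -1.82 within slide 3, although the sign was kept in both. Against the Control mean, the siRNA 2 arrays stood at -0.97 and -1.05 on these slides, and the Control arrays at -0.57 and 0.48. The move thus lay mainly in the Control arrays. A part of the difference may come from the slide or from spread between Control samples, which cannot be told apart here. Position on the slide cannot be told apart from the siRNA, since 0 groups lay at more than 1 position. A second list of visceral endoderm markers, written after the pattern and before its values were seen and sharing 0 genes with the 29 lists, had a median of -0.56 with 14 of 17 members lower (S100g at -1.97, Spink1 at -1.47, but Rbp4 at -0.05, Trf at 0.20 and Fgg at 0.32, genes chosen after their values were seen), so fewer visceral endoderm cells under siRNA 2 remain a possible explanation beside a change within cells, which was not tested.

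The replicate 1 arrays, all on slide 1, stood apart from the other arrays. The replicate 1 differences of Control and siRNA 1 correlated across genes at 0.41 among the dimmest 7475 genes. The correlation was 0.23 among the middle and -0.23 among the brightest. A shared part in the dimmer genes alone is what an effect on dim probes and array signal would give. Such an effect does not cover the opposite deviations among the brightest genes, whose cause was not tested. The siRNA 2 arrays had no part in these correlations by brightness. Over all genes, the replicate 1 deviations from the group mean correlated at 0.65 between siRNA 1 and siRNA 2, against 0.32 between Control and each siRNA. Foxp3, a gene of regulatory T cells chosen after its values were seen, was lower on slide 1 by a log2 difference of -2.51. Whether slide or culture set replicate 1 apart cannot be told apart, because these arrays lay on 1 slide.

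The value table's Control 2 and Control 3 columns correlated across probes with each other's scanner values at 1. The higher of the correlations with their own scanner values was -0.049. The 2 names are thus exchanged between the value table and the scanner files. Which naming is right is not known, and no biological explanation was tested. With the table's names, arrays of the same replicate number would share a slide, so the replicate numbers and the slides would split the arrays in the same way.

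Other groupings of the arrays were drawn as well. Of 100 relabellings into groups of 3, 3 and 2, the real one included, all 100 gave at least the 0 genes of the mean comparison, which any relabelling must, so the share says nothing about that count. The highest, 1622 genes, came from a relabelling that made slide 1 a group, which points to a structure of the samples. For the 10 shifted lists at the preset correlation, 3 of the 100 gave as many, a share under 0.05. The draws ignored the slide, which sets arrays apart, so this share cannot exclude a random grouping. The 3 were the real one, one with 10 lists that kept the same Control arrays, and the highest with 12, again with slide 1 as a group. The median was 4 lists. With slide as a block 8 lists shifted. For siRNA 1 against Control, 3 against 3 arrays make 10 splits, too few for a share under 0.05. The real split gave 0 genes and the highest other 0, so that 10 of 10 as large was fixed beforehand. It gave 5 lists and the highest other 10, with 4 of 10 as large.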

How the results depend on the processing

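Leaving out the slide 1 arrays was chosen after seeing the data, as was counting a list as reversed when its median alone changed sign, which holds for 5 of the 8 below. The counts of 0 genes held under most alternatives. For the mean comparison, array weights gave 23 genes, the arrays without slide 1 gave 1, and leaving out 1 array gave 0 to 2. For siRNA 2 against Control the last 2 settings gave 1 and 0 to 5, and for siRNA 2 against siRNA 1 they gave 1 and 0 to 4, with 1 when only the groups compared were fitted. Those calls arose without siRNA 2 replicate 1 (1, 2 and 2 genes, all unnamed here) or without siRNA 2 replicate 2 (2, 5 and 4 genes, among them Fbf1, Tmed8 and Cyp2s1, chosen after their values were seen), where the lone siRNA 2 array is assumed to vary like the other groups. For siRNA 1, and for genes moved the same way by both, leaving out 1 array gave 0 to 0 genes. The 10 shifted lists became 6 under normexp and 6 under array weights, 0 with an estimated correlation and 0 with fry, and 5 to 11 with 1 array left out (5 without Control replicate 1 and 5 without siRNA 1 replicate 2). The cause was not tested, except that the set tests with 0 calls allow for correlation between genes.

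The ribosomal median reversed under quantile normalization, to -0.0098 for the mean, -0.00037 for siRNA 1 and -0.0021 for siRNA 2, and under normexp to -0.011 for the mean and -0.024 for siRNA 2. The Nodal median for the mean reversed to 0.011 without siRNA 1 replicate 2 and to 0.0088 without siRNA 2 replicate 2 (-0.14 to 0.011 with 1 array left out), and the epiblast median between siRNAs to -0.060 without siRNA 2 replicate 2 (-0.060 to 0.17). The cause was not tested. Of 644 values of 28 list calls under alternatives, 547 kept their call, 89 lost it and 8 reversed. Of 2889 values of named genes, 2835 kept sign and side, 8 became calls and 46 turned sign without a call. Sizes moved more: 78 of 126 named results moved by over 1.5 times under some setting, 54 under normexp and 42 without background correction, which by construction compress dim signals, 36 without the slide 1 arrays, 24 without Control replicate 1 and 20 without Control replicate 2. The replicate block left 0 genes and gave 8 lists. Across genes, deviations of same-numbered arrays from their group correlated between -0.04 and 0.65. The values near the low end involved Control 2 and Control 3, whose names differ between the value table and the scanner files. Arrays of the same slide correlated between 0.04 and 0.65. The labels do not say what a shared number means, so the numbers were not read as pairs, and the main fit left the slide out. Signal over background at the 75th percentile was 16.9 to 24.5, and dim genes such as Afp under siRNA 2 have only bounds.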

Other observations

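Parietal endoderm genes, in a list written after the endoderm pattern was seen and before the values of its genes were, stood lower in 8 of 8 measured members under siRNA 2 and in 7 of 8 under siRNA 1. The medians were -0.55 and -0.37, with camera's unadjusted p of 7.62e-06 and 0.000305, or 0.123 and 0.194 with an estimated correlation. Both siRNAs were set against the same Control arrays, so their results for this list are not independent. The members with the smallest p in limma under siRNA 2 were Srgn, which encodes serglycin, at -1.50 ± 0.46 (SE) and Serpinh1, a collagen chaperone, at -0.74 ± 0.23 (SE). The visceral list written in the same way had a median of 0.03 under siRNA 1.

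Some values came from 1 array and were chosen after they were seen. Actc1, the cardiac actin, stood 2.49 above the Control mean on Control 1, and between -1.91 and -1.04 on the 7 other arrays. Fbf1, a centriole protein gene, differed from Control by a log2 value of 8.22 on siRNA 2 replicate 1, and the siRNA 2 arrays had an SD of 5.72. Tmed8 differed by 6.65 on that array, with an SD of 4.68 over the siRNA 2 arrays.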
